A study of Mus musculus with 5 samples.

How the data were processed

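RNA from 5 cell populations of wild-type C57Bl/6 mouse bone marrow was measured on expression arrays, 1 array per population. Per the labels' protocols, the cells were purified by flow cytometry and used without treatment, RNA was extracted with the RNAqueous-Micro kit, and it was biotin-labelled with the Nugen Encore kit. All 5 populations lacked the lineage markers and carried CD115, the receptor encoded by Csf1r. The monocyte-dendritic cell progenitor (MDP) carried CD117 and CD135, the common dendritic cell progenitor (CDP) had intermediate CD117 with CD135, and the common monocyte progenitor (cMoP) had CD117 without CD135. CD117 is encoded by Kit and CD135 by Flt3. Classical monocytes were sorted as Ly6C-positive and TremL4-negative cells, and nonclassical monocytes as Ly6C-negative and TremL4-positive cells. Groups were taken from the sample titles in the labels.

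The deposited table holds 1 log2 value for each of 35556 probe sets on each array. The log2 scale was read from the values, which run from 1.59 to 14.24 and so stay under the upper limit of a 16-bit scanner on a base 2 scale. Background correction, normalization, summarization of probes and software are not given in the sources used here, and the base of the logarithm is not stated either. If the base or scale were another, each fold given here would change with it. The array medians over all probe sets were 6.14 for MDP, 6.13 for CDP, 6.02 for cMoP, 6.07 for classical monocytes and 6.16 for nonclassical monocytes. They lie close together but are not equal, and whether and how the arrays were scaled stays unknown. Many values are exactly tied between arrays. In 16564 probe sets (46.6%) 2 or more arrays hold the same value to the last digit, and 1098 probe sets are equal on all 5 arrays. Among the 6602 probe sets with 1 tied pair, the tie lies at the middle of the ordered values in 98.97%, where 50% would be met by chance. There were 53324 tied pairs of values, against 373 pairs that differed by less than 0.001. Small differences between arrays may have been removed by this feature of the table, whose origin is not given in the sources used here.

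Probe sets were named from the platform's annotation table. Of the 35556 probe sets, 21789 carry 1 gene symbol, 1621 carry several and 12146 are not listed there. The Entrez identifiers of 21698 of the 21789 were found in a RefSeq gene table (assembly GRCm38.p6, used for names only), and 0 symbols changed by that match. Genes were named from probe sets with 1 symbol, which gave 19938 genes. For the 999 genes with several probe sets, the probe set with the highest mean over the 5 arrays was used. The array's genome build is not named in the sources used here, and no coordinates are given.

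A difference is the log2 value of the first population minus that of the second, so 1 log2 unit is 2-fold and 2 log2 units are 4-fold. Where the lower value of a named gene lay under the floor described next, its fold was computed with that value set to the floor and is given as at least that size, while the log2 difference is that of the deposited values. A gene was counted as higher or lower where the difference was 1 log2 unit or more and the higher of the 2 arrays was at or above a floor, the median of all named genes' values over the 5 arrays (6.27). The comparisons were CDP with MDP, cMoP with MDP, cMoP with CDP, classical monocyte with cMoP and nonclassical with classical monocyte. A gene led a population where its value there was at least 1 log2 unit above the next array. A progenitor gene was one whose lowest value over the 3 progenitor arrays was at least 1 log2 unit above the higher monocyte array, and a monocyte gene was the reverse over the 2 monocyte arrays. There are no replicates, so the differences have no replicate check, no p-values or standard deviations were computed, and the number of arrays limits the precision of every value.

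The 29 gene lists, the comparisons, the threshold, the floor, the alternatives and the rule for naming genes were fixed before the data were examined. The lists cover sort genes, classical and nonclassical monocyte genes, stem and early progenitor genes, 3 groups of conventional dendritic cell genes, plasmacytoid dendritic cell genes, class II presentation, primary granules, DNA replication, mitosis, ribosome biogenesis, interferon-stimulated genes, lysosome, cholesterol synthesis, immediate early genes, trafficking and adhesion, pattern recognition, Fc and complement receptors, myeloid transcription factors and sex-linked transcripts. Lists for neutrophils, erythroid cells, megakaryocytes and platelets, B cells, T and NK cells, macrophages, and basophils, mast cells and eosinophils stand for other cells a marrow sort could hold. Of 518 written members 472 were measured, 1 of them under an older symbol. The other 46, among them Ly6c1, Ly6c2, Isg15, Ccnb1 and the hemoglobin genes, had no probe set with a single symbol and were not used here. A gene can stand in more than 1 list.

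For each list the median difference of all measured members was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called shifted where its percentile was under 2.5 or over 97.5 and it had at least 5 members. The percentile describes these arrays and is no test of the populations. Random lists treat genes as independent, so lists of co-regulated genes reach the extremes more easily. Members under the floor in both arrays stay in the median and are left out of the counts of higher and lower members. The code was checked on lists of random genes, with the differences between CDP and MDP permuted within the expression bins (19938 genes, 200 lists per setting). The procedure called 5% of lists of 10 and 5.5% of lists of 20 genes with no shift, a rate that this design sets in advance. With the same shift of 0.3 log2 units added to every member it called 99% and 100%. The check does not show how the procedure behaves on lists of co-regulated genes with unequal shifts, and it used fewer random lists.

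Genes named in the text are the 10 with the largest difference in each direction past the floor, leaving out predicted or uncharacterised genes, microRNAs, small nucleolar RNAs, olfactory and vomeronasal receptors and antigen receptor segments. The genes of the sorting markers, up to 4 members of each list with the largest difference past the floor, members past 1 log2 unit against a list's direction, and the 5 leading genes of each population with the widest gap are also named. The 10 progenitor and 10 monocyte genes with the widest gap are given as well, a choice made after the values were seen. The alternatives were quantile normalization, centring each array on its median, no floor, a floor at the upper quartile (7.93), a threshold of 2 log2 units and the mean of a gene's probe sets. For lists they were also the removal of genes another list holds and of members under the floor on every array. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.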

Results

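The series profiles 5 stages of mononuclear phagocyte development in mouse marrow: a progenitor shared by monocytes and dendritic cells (MDP), a progenitor of each branch (CDP for dendritic cells, cMoP for monocytes), and the classical and nonclassical monocyte. Each population has 1 array, and between 9831 and 10167 of the 19938 named genes lay at or above the floor of 6.27 on each. Differences are in log2 units, with negative values for genes lower in the first population named. Of the 20 genes with the largest differences in each comparison, the lower value lay under the floor for 10, 15, 13, 11 and 17 in the order given below. The size and order of such differences depend on dim signal, and a fold for them is given as a bound with the lower value set to the floor. Across genes, which are not independent replicates, the arrays of MDP and CDP correlated at r = 0.988, MDP and cMoP at 0.987, and CDP and cMoP at 0.980. The correlation was 0.965 between cMoP and the classical monocyte, 0.948 between the 2 monocyte arrays and 0.901 between MDP and the nonclassical monocyte. CDP correlated with the classical monocyte at 0.968 and with the nonclassical one at 0.919, where cMoP had 0.965 and 0.904. By this measure the cMoP array was thus not the progenitor array nearest to the monocytes. The median absolute log2 difference gave another order for the classical monocyte, with 0.1319 for MDP, 0.136 for cMoP and 0.1503 for CDP. For the nonclassical monocyte it was 0.195 for CDP, 0.217 for cMoP and 0.2296 for MDP. Which progenitor array lay nearest to the classical monocyte thus depends on the measure, and cMoP was nearest by neither.

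The measured genes of the sorting markers followed the gates. Ly6c1 and Ly6c2 were not measured, so the Ly6C side of the monocyte gates was not checked. Csf1r, the receptor for colony-stimulating factor 1, was high on all 5 arrays, from 10.03 in cMoP to 12.21 in nonclassical monocytes. Kit, the stem cell factor receptor, had values of 10.11 in MDP, 8.16 in CDP and 9.37 in cMoP, against 5.79 and 5.61 in classical and nonclassical monocytes. Flt3, the receptor for the dendritic cell growth factor Flt3 ligand, had values of 10.75 in MDP and 10.74 in CDP and of 6.4 in cMoP. Treml4 was at 11.78 in nonclassical monocytes and between 5.02 and 6.18 on the other 4 arrays. Because these markers defined the gates, their differences check the labels. The list of sort genes has 4 measured members, too few to be called in any comparison. Among the sex-linked transcripts Xist was between 10.98 and 12.11 on all arrays, while the Y-linked Kdm5d, Eif2s3y and Uty were between 2.55 and 4.19. Xist was lower in cMoP than in MDP by a difference of -1.12, and that list also has 4 members and was not called.

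**Figure D1:**
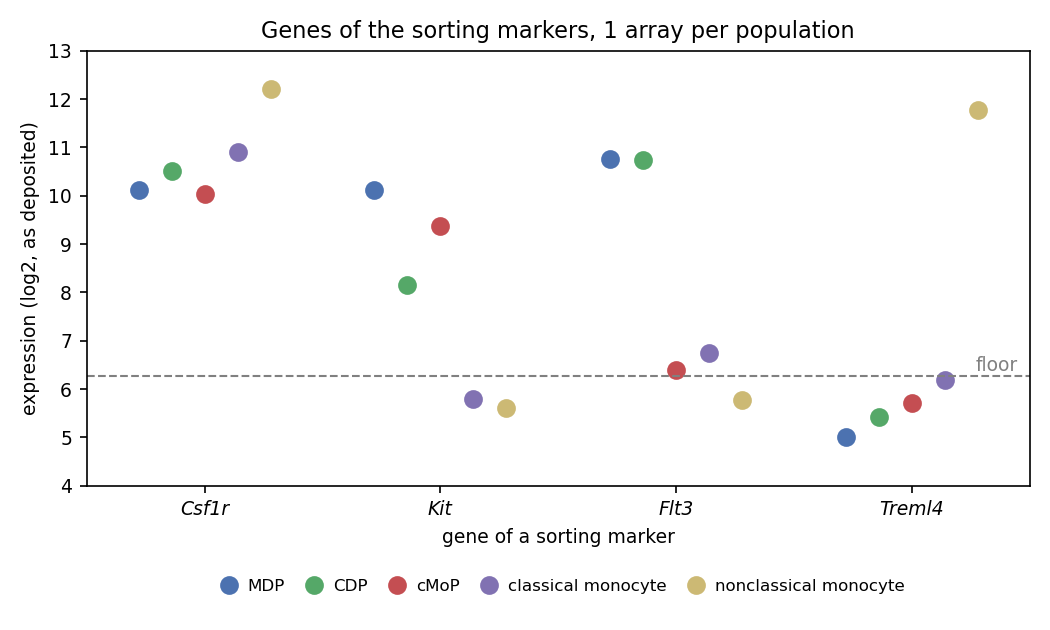
Log2 expression (vertical axis) of the 4 measured genes of the sorting markers (horizontal axis), with 1 point per array coloured by population and a dashed line at the floor of 6.27. Flt3 is at 10.75 and 10.74 in MDP and CDP and at 6.4 in cMoP, and Treml4 is at 11.78 in nonclassical monocytes alone among the 5 arrays.

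The first comparison asked how the progenitor of dendritic cells differed from the shared progenitor. CDP had higher values than MDP for genes of dendritic cells and of antigen presentation, and lower values for genes of stem cells, of primary granules and of ribosome assembly. Clec9a, a receptor of type 1 conventional dendritic cells for dead cell material, was 5.91-fold higher (2.56). Siglech, a surface lectin of plasmacytoid dendritic cells, was higher by 1.98. Angpt1, the angiopoietin made by early progenitors, was at least 3.34-fold lower (-2.43), and Elane, the gene of neutrophil elastase, was 4.32-fold lower (-2.11). In all, 120 genes were higher and 110 lower of the 10416 past the floor, and 21 and 7 of them differed by 4-fold or more. Which side was larger depends on the setting, since centring gave 100 higher and 137 lower and a floor at the upper quartile 80 and 61.

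The largest positive difference was that of Cd7, a surface glycoprotein of lymphoid cells, at 3.21 (at least 8.57-fold). It was followed by Rnase6, an antimicrobial ribonuclease, at 3.06, Rnd3 at 3.05, and Lilra6, an immunoglobulin-like receptor, at 3.03. L1cam, an adhesion molecule, was higher by 2.71, Lgals3, which encodes galectin-3, by 2.65, and Serpinb10, a serine protease inhibitor, by 2.63 (at least 1.81-fold). S100a6, a calcium-binding protein, and Fn1, the gene of fibronectin, were higher by 2.52 and 2.44. At the other end, Ms4a3, a membrane protein of granulocyte and monocyte progenitors, differed by -2.6, Atxn1 by -2.57 and Nkg7, a granule membrane protein, by -2.20. Cxcr2, a chemokine receptor of neutrophils, differed by -2.18, Mc5r, a melanocortin receptor, by -2.02 and Adgrl4, an adhesion receptor, by -1.97. Kit and Clec4e, the receptor for mycobacterial cord factor, differed by -1.95 and -1.94, but Clec4e was just past the floor in MDP (at least 1.07-fold).

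Of the 12 plasmacytoid dendritic cell genes past the floor, 6 were higher and 1 lower (list median 0.73). The 6 included Cd300c (2.16), Tlr9 (1.35) and Smim5 (1.24), and the lower one was Dntt (-1.20), the template-independent DNA polymerase of lymphoid precursors. The list of genes shared by conventional dendritic cells had 2 of 7 higher, the transcription factor Id2 (1.72) and the integrin Itgax (1.58), with a median of 0.48. Type 1 genes had 2 of 6 higher, Clec9a and the lysosomal amidase Naaa (1.83), with a median of 0.32. Type 2 genes had 3 of 6 higher, Klf4 (2.21), Cd209a (2.05) and Kmo (1.77), with a median of 0.25. Class II presentation genes had 3 of 8 higher, namely H2-Aa (1.58), the invariant chain Cd74 (1.44) and H2-Ab1 (1.04, and 0.99 after centring), with a median of 0.58. All 5 of these lists lay past the upper percentile limit of matched random lists. Some of their higher members were higher still in classical monocytes than in CDP, among them Klf4 (9.47 against 8.79), Naaa (10.8 against 8.22) and Id2 (9.70 against 8.01). Others, among them Clec9a, Cd300c, Cd209a, Kmo, Itgax, H2-Aa and H2-Ab1, were highest in CDP of the 5 arrays.

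Stem and early progenitor genes had 8 of 17 lower and 0 higher, with a median of -0.76. They included Meis1 (-1.49), a transcription factor of stem cells, Cd27 (-1.33) and Cd34 (-1.31). Primary granule genes had 4 of 12 lower, among them Ctsg (-1.04, and -0.94 after quantile normalization), the gene of cathepsin G, with a median of -0.66. Ribosome biogenesis genes had 4 of 21 lower, Myc and Wdr12 (both -1.27), Gnl3 and Dkc1 (both -1.11), with a median of -0.80. These 3 lists lay under the lower limit. Mitosis genes had 0 of 21 past the threshold and a median of 0.11, called although small, and DNA replication genes had 0 of 23 and a median of -0.13, not called.

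Several lists of broader myeloid function were also called higher in CDP than in MDP. Trafficking and adhesion genes had 4 higher and 1 lower of 17 (median 0.31), with Itgb2 (1.74) and Itgb7 (1.52) higher and Cxcr2 lower. Fc and complement receptor genes had 1 higher and 1 lower of 7 (median 0.39), Fcgr3 being at -1.30. Immediate early genes had 1 of 17 higher, Klf6 (1.32), with a median of 0.24. Myeloid transcription factors had 4 of 30 higher, Klf4, Id2, Nfil3 (1.22) and Irf5 (1.01, and 0.95 after centring), with a median of 0.20. Lysosome genes had 3 higher and 1 lower of 22 (median 0.17), with Ctsh (1.40) and Psap (1.21) higher and Cd63 at -1.62. Pattern recognition genes had 1 higher, Tlr9, and 2 lower, Clec4e and Clec4d (-1.08), of 14 (median 0.11), and classical monocyte genes 3 higher and 1 lower of 13 (median 0.09), the 3 being Fn1, Tgfbi (1.40) and Ifitm6 (1.27). Nonclassical monocyte genes (0.05), interferon-stimulated genes (0.01, with Rtp4 at -1.68) and cholesterol synthesis genes (0.00) were not called. The calls of the classical monocyte and pattern recognition lists ended with quantile normalization, and that of the type 2 list without genes that other lists hold.

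The second comparison set the progenitor of monocytes against the shared progenitor. cMoP had higher values for classical monocyte, primary granule and pattern recognition genes and lower values for stem and early progenitor genes. S100a8, a calcium-binding protein abundant in neutrophils and monocytes, was at least 31.2-fold higher (5.12), and Chil3, a chitinase-like secreted protein, at least 6.18-fold higher (3.64). Dntt was at least 10.1-fold lower (-5.71) and Flt3, a gene of the gate, 20.4-fold lower (-4.35). In all, 147 genes were higher and 143 lower of 10235 past the floor, with 23 and 20 at 4-fold or more. The near-even split depends on the setting, since a floor at the upper quartile gave 111 higher and 73 lower and quantile normalization 161 and 121.

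Clec4a2, a C-type lectin receptor, was higher by 3.22, Mcemp1, a membrane protein of mast cells and monocytes, by 2.98, Ly6a2 by 2.90 and Adgre5, the adhesion receptor CD97, by 2.90. Gda, guanine deaminase, was higher by 2.88, and Lcn2, an iron-siderophore carrier, by 2.83. Fcgr3, a low-affinity receptor for immunoglobulin G, and Sgms2, a sphingomyelin synthase, were each higher by 2.73. On the lower side stood Angpt1 (-2.97), Ctla2a (-2.52), Gimap6 (-2.45), an immune GTPase, and Aff3 (-2.36). Il7r, a cytokine receptor of lymphoid precursors, was at -2.36 (at least 1.22-fold), Marcks, an actin-regulating substrate of protein kinase C, at -2.35, Cd27 at -2.25 and Clec9a at -2.19.

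Classical monocyte genes had 7 of 16 higher and 0 lower, with a median of 0.61. Beside Chil3 and Gda they were Hp (2.32), Mgst1 (1.75), Tgfbi (1.66), Lyz2 (1.39) and Ifitm6 (1.23). Primary granule genes had 5 of 14 higher and a median of 0.68, the 5 being Fcnb (2.36), Ms4a3 (2.29), Gstm1 (1.94), Nkg7 (1.74) and Elane (1.45). Pattern recognition genes had 2 higher and 1 lower of 16 (median 0.60), with Clec5a (2.45) and Tlr4 (1.93), the receptor for lipopolysaccharide, higher and Tlr7 at -2.05. Lysosome genes had 3 higher and 1 lower of 22 (median 0.48), with Cd63 (1.52) and Ctsh (1.14) higher and Lgmn at -1.07 (-0.92 after quantile normalization). Fc and complement receptor genes had 2 of 7 higher (median 0.32), and cholesterol synthesis genes 0 of 14 (median 0.20). All of these were called.

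Stem and early progenitor genes had 8 of 17 lower and 0 higher in cMoP, with a median of -0.91, among them Adgrg1 (-2.16), Sox4 (-1.79) and Meis1 (-1.49). Interferon-stimulated genes had 1 of 12 lower, Rtp4 (-2.07), and a median of -0.40. Class II presentation genes had 2 of 7 lower, Cd74 (-1.65) and H2-Ob (-1.31), with a median of -0.24. Plasmacytoid genes had 3 of 10 lower, Dntt, Il7r and Tcf4 (-1.07), with a median of -0.14, and genes shared by conventional dendritic cells had 2 of 6 lower, Dpp4 (-1.45) and Nav1 (-1.16), with a median of -0.14. The lists for mitosis (-0.12), ribosome biogenesis (-0.13) and type 1 dendritic cells (-0.05) were called with no or few members past the threshold, and the last had a median of 0.02 after quantile normalization and of 0.00142 without genes that other lists hold. In that list Clec9a was lower and Naaa was at 1.14. Type 2 dendritic cell genes, immediate early genes and myeloid transcription factors had medians of 0.00, nonclassical monocyte genes likewise, DNA replication genes 0.19 and trafficking genes 0.12, none of them called. Of the transcription factors, Klf4 (1.88), Id1 (1.28) and Cebpb (1.10) were higher and Tcf4 lower. The calls of the ribosome biogenesis and cholesterol lists ended with the mean of a gene's probe sets, and that of the type 1 list also without members under the floor on every array.

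The comparison between the 2 committed progenitors was the widest among the progenitor arrays, with 337 genes higher in cMoP and 230 lower of 10441 past the floor, and 40 and 45 at 4-fold or more. A floor at the upper quartile gave 250 and 149. Genes of primary granules were higher in cMoP and genes of dendritic cells were higher in CDP. Ms4a3 was 29.7-fold higher in cMoP (4.89), Elane 11.8-fold (3.56) and Fcgr3 16.3-fold (4.03). Clec9a was at least 12.1-fold lower (-4.76), Dntt at least 4.42-fold lower (-4.52) and Cd7 at least 8.57-fold lower (-3.42).

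S100a8 (4.09), Nkg7 (3.94), Trem3 (3.67), an activating receptor of myeloid cells, and Gda (3.54) were also among the genes with the largest positive differences. Hdc, the enzyme that makes histamine, and Chil3 were each higher by 3.29, and Hp, the gene of haptoglobin, by 3.21. The largest negative differences further included Flt3 (-4.34), Ifi205 (-4.31), an interferon-inducible gene, Plbd1 (-3.46), a phospholipase-like lysosomal protein, and Klrd1 (-3.45), a lectin-like receptor of NK cells. Rnd3 (-3.35), Samd9l (-3.23) and Rtn4rl1 (-3.11) completed them.

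Primary granule genes had 10 of 14 higher in cMoP and 0 lower, with a median of 1.35. They included Gstm1 (2.94), Ctsg (1.54) and Prtn3 (1.38), the gene of proteinase 3. Ribosome biogenesis genes had 4 of 21 higher, Nop16 and Wdr12 (both 1.18), Nolc1 (1.09) and Gnl3 (1.03), with a median of 0.58, and after quantile normalization Nolc1 and Gnl3 were at 0.99 and 0.90. Classical monocyte genes had 5 higher and 1 lower of 16 (median 0.36), with Mgst1 (2.70) and Clec4e (2.54) higher and Fn1 at -2.05. Lysosome genes had 1 higher, Cd63 (3.14), and 1 lower, Lgmn (-1.88), of 22 (median 0.40). Pattern recognition genes had 5 higher and 1 lower of 15 (median 0.27), with Clec5a (2.78) and Tlr4 (2.12) higher and Tlr9 at -1.27, and DNA replication genes had 0 of 23 past the threshold (median 0.35).

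Plasmacytoid dendritic cell genes had 9 of 12 lower in cMoP and 0 higher, with a median of -1.04. Beside Dntt they included Il7r (-2.75), Siglech (-2.54) and Tcf4 (-1.52), a transcription factor of plasmacytoid cells. Genes shared by conventional dendritic cells had 4 of 7 lower, Id2 (-2.40), Dpp4 (-1.92), Itgax (-1.77) and Nav1 (-1.18), with a median of -0.65. Class II genes had 3 of 8 lower, Cd74 (-3.10), H2-Aa (-2.13) and H2-Ab1 (-1.40), with a median of -0.59. Type 2 genes had 2 of 6 lower, Cd209a (-2.6) and Kmo (-2.37), with a median of -0.43, and type 1 genes 1 of 6, Clec9a, with a median of -0.34. Interferon-stimulated genes had 1 of 12 lower, Irf7 (-1.04, but -0.93 after quantile normalization and -0.98 after centring), with a median of -0.45.

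Mitosis genes had 2 of 21 lower, Mki67 (-1.04) and Cenpf (-1.01), with a median of -0.25, but centring put both within the threshold, at -0.98 and -0.95. Immediate early genes had 3 of 17 lower, Dusp1 and Zfp36 (both -1.56) and Btg2 (-1.25), with a median of -0.27. Trafficking genes had 1 higher and 3 lower of 17 (median -0.22), with Cx3cr1 at -1.80 and Cxcr2 at 1.51. Myeloid transcription factors had 2 higher, Cebpe (1.09) and Id1 (1.08), and 5 lower of 31, with Id2, Bach2 (-1.67) and Bcl6 (-1.04) among them, and a median of -0.15. Fc and complement receptor genes had a median of -0.24 but a mean of 0.25, with Fcgr3 and Fcgr4 (1.52) higher and Itgax lower. Fcgr4 was at 6.30 in cMoP, just past the floor. Stem and early progenitor genes (0.00), nonclassical monocyte genes (-0.06, with Fcgr4 and Pglyrp1 at 1.60 higher) and cholesterol synthesis genes (0.00) were not called. The DNA replication call ended with quantile normalization, the Fc and complement receptor call with that and with both changes of membership, and the transcription factor call without genes that other lists hold.

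A block of 6617 probe sets that the annotation does not list, all with identifiers before the first listed one, was lower on the cMoP array. Its median was 5.70 in cMoP, against 6.25 in MDP, 6.04 in CDP, 6.15 in classical and 6.30 in nonclassical monocytes. Of its 3387 probe sets past the floor in the comparison with MDP, 714 were lower and 55 higher in cMoP. With CDP the numbers were 628 and 179, and in classical monocytes against cMoP 587 were higher and 66 lower. The targets of these probe sets are not given in the sources used here, and they enter no gene count.

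**Figure D2:**
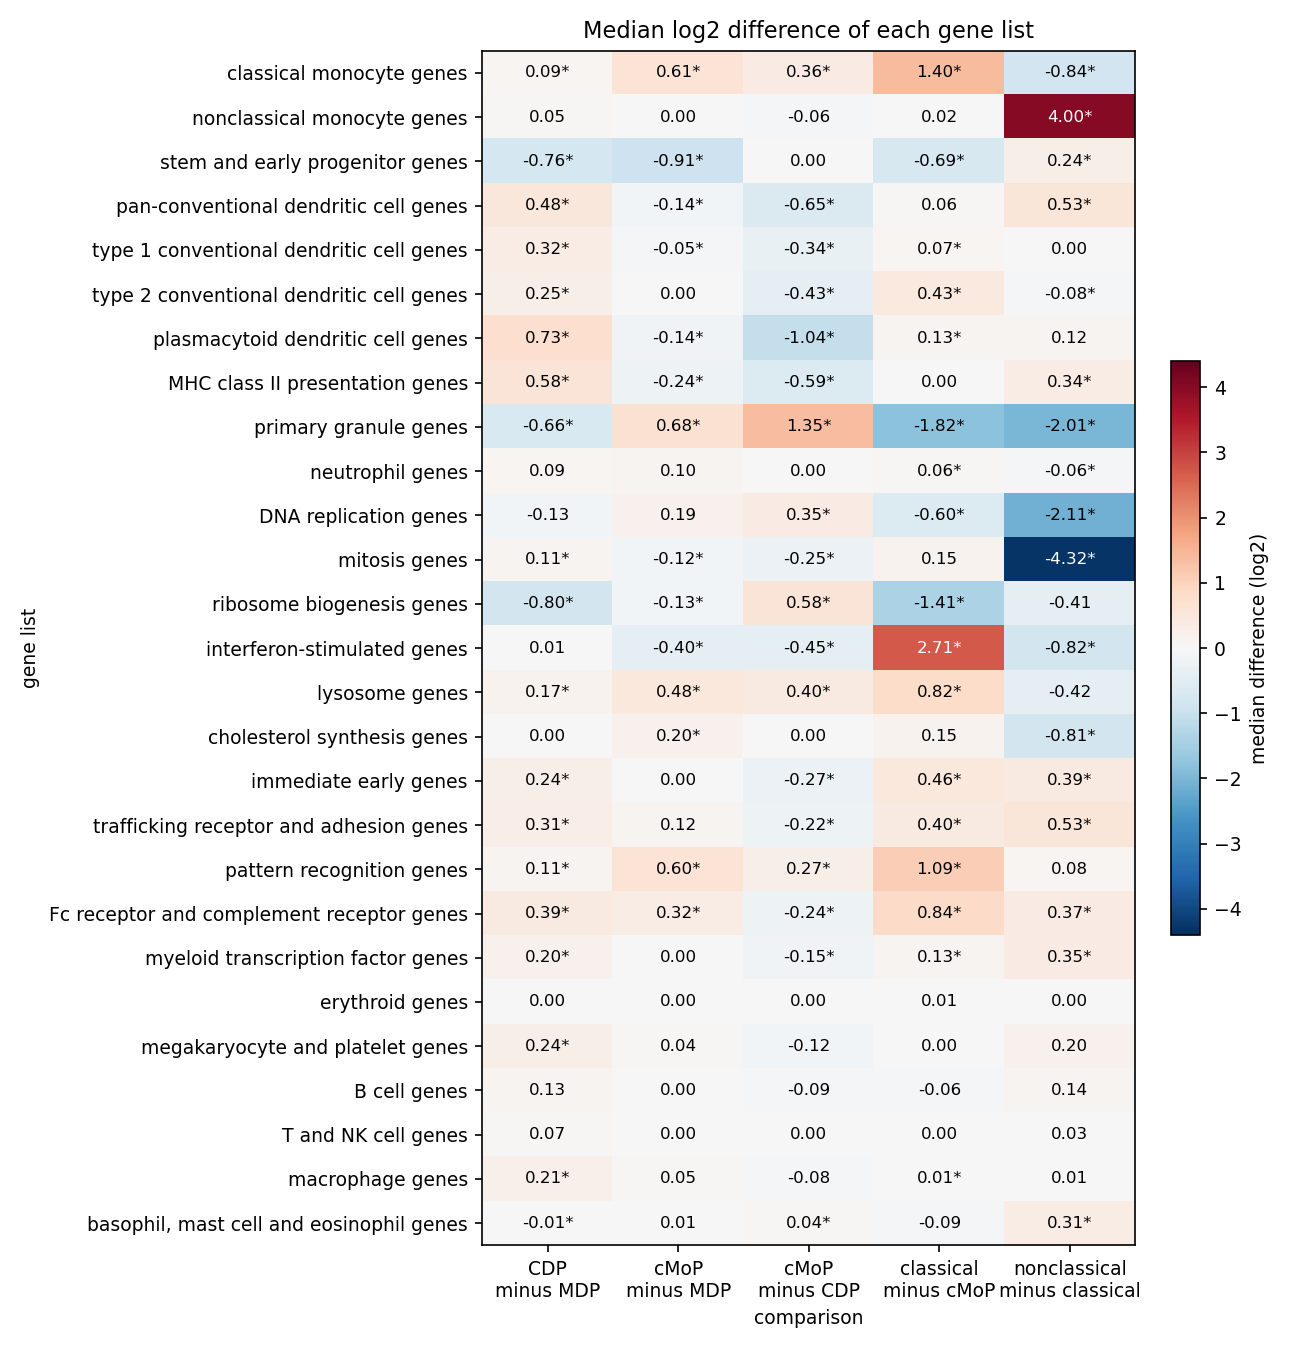
Median log2 difference of 27 gene lists (vertical axis) in the 5 comparisons (horizontal axis), with red for higher and blue for lower in the first population named, and an asterisk for lists past a percentile limit of matched random lists. The widest medians are those of the mitosis genes (-4.32) and the nonclassical monocyte genes (4.0) in nonclassical against classical monocytes, and of the interferon-stimulated genes (2.71) in classical monocytes against cMoP.

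The step from cMoP to the classical monocyte was compared next. Classical monocytes had higher values for classical monocyte, pattern recognition and interferon-stimulated genes, and lower values for genes of primary granules, ribosome assembly and stem cells. Klra2, a lectin-like receptor of the Ly49 family, was at least 21.5-fold higher (5.99), and Fn1 39.4-fold higher (5.30). Nkg7 was 23.4-fold lower (-4.55), Cd34 11.9-fold lower and Kit at least 8.6-fold lower (both -3.58). In all, 722 genes were higher and 453 lower of 10305 past the floor, with 197 and 57 at 4-fold or more.

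Plbd1 (5.75), the lectin receptors Clec4a1 (5.71) and Clec4a3 (5.32), and the scavenger receptor Msr1 (5.55) were among the largest positive differences. Samd9l, Wfdc17 and Lilrb4a, an inhibitory immunoglobulin-like receptor, were higher by 5.50, 5.46 and 5.05. Tlr13, a sensor of bacterial ribosomal RNA, was higher by 5.04. The largest negative differences included Ms4a3 (-4.53), Prss57 (-3.90), a granule serine protease, Cd63 (-3.56), a tetraspanin, and Ccnd2 (-3.30), a cyclin of the first gap phase. Cst7, an inhibitor of cysteine proteases, Hdc and Adgrg3 were at -3.28, -3.25 and -3.24.

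Interferon-stimulated genes had 18 of 20 higher in classical monocytes and 0 lower, with a median of 2.71. Rtp4 (4.24), Ifit3 (4.13), Irf7 (3.55) and Zbp1 (3.27) had the largest differences. Classical monocyte genes had 14 of 18 higher and 0 lower (median 1.40), led after Fn1 by Vcan (4.59), a matrix proteoglycan, Mmp8 (4.26), a collagenase, and Chil3 (3.90). Pattern recognition genes had 12 of 18 higher and 0 lower (median 1.09), with Tlr7 (4.26) and Tlr8 (3.13), both sensors of single-stranded RNA, after Tlr13. Fc and complement receptor genes had 3 of 9 higher, Itgam (3.60), Fcgr1 (2.40) and C5ar1 (2.16), with a median of 0.84. Lysosome genes had 7 higher and 2 lower of 22 (median 0.82), with Ctss (2.45) and Cd68 (2.33) higher and Cd63 and Gaa (-1.03) lower. Immediate early genes had 7 of 18 higher, with Btg2 (2.40) and Zfp36 (2.34) in front (median 0.46). Trafficking and adhesion genes had 7 higher and 2 lower of 17 (median 0.40), with Ccr1 (3.89), Itgam and Itgb2 (2.88) higher and Pecam1 (-1.83) and Cxcr2 (-1.37) lower.

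Primary granule genes had 9 of 14 lower (median -1.82). They included Mpo (-2.42), the gene of myeloperoxidase, and Elane (-2.35), while Fcnb was at 1.10. Ribosome biogenesis genes had 14 of 21 lower and 0 higher (median -1.41), with Myc (-2.80), Gnl3 (-2.47) and Wdr12 (-2.23) in front. Stem and early progenitor genes had 8 of 14 lower and 0 higher (median -0.69), among them Myb (-2.57) and Adgrl4 (-2.33). DNA replication genes had 0 of 23 past the threshold and a median of -0.60, which was called, and Uhrf1 (-0.92) had the largest difference. Mitosis genes also had 0 of 21 past the threshold, with a median of 0.15 at percentile 88.0, and were not called. Mki67 differed by 0.63 and Ccnb2 by 0.38.

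Among the dendritic cell lists, type 2 genes had 5 of 8 higher, with Irf4 (2.04), Sirpa (1.45) and Clec10a (1.08) in front (median 0.43). Plasmacytoid genes had 3 of 8 higher, Irf7, Tlr9 (1.87) and Smim5 (1.47), with a median of 0.13, and type 1 genes had 1 of 5, Naaa (3.22), with a median of 0.07, and all 3 lists were called. Genes shared by conventional dendritic cells had 3 of 6 higher, Id2 (4.10), Btla (1.92) and Nav1 (1.18), with a median of 0.06, and class II genes 1 of 7, Cd74 (2.66), with a median of 0.00, neither of them called. Myeloid transcription factors had 9 higher and 2 lower of 31 (median 0.13, called), with Id2, Bcl6 (2.6) and Irf5 (2.44) higher and Myb and Tcf7l2 (-1.10) lower. Nonclassical monocyte genes had 6 higher and 1 lower of 17 (median 0.02), led by Adgre4 (2.78) and Gngt2 (2.35), and with cholesterol synthesis genes (0.15) were not called. The trafficking call ended without genes that other lists hold, and the type 1 call without members under the floor on every array. Of 126 other probe sets of counted genes with several, 97 had the same direction as the one used, the lowest share among the comparisons. Several of the named genes, such as those of the Clec4a, Klra, Lilr and Ly6 families, have close relatives whose signals an array can mix.

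The last comparison set the 2 monocyte subsets against each other and gave the widest difference. Nonclassical monocytes had higher values for the genes that mark this subset, and lower values for genes of cell division, of granules and of the classical subset. Cd36, a scavenger receptor for oxidised lipids, was at least 27.0-fold higher (6.28), and Fabp4, a fatty acid carrier, at least 11.1-fold higher (6.22). F13a1, the A chain of coagulation factor XIII, was at least 62.6-fold lower (-7.19), and Kif11, the motor that separates spindle poles, at least 18.6-fold lower (-6.18). In all, 373 genes were higher and 1031 lower of 10503 past the floor, with 116 and 313 at 4-fold or more.

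Lilra5 (5.43), Fcgr4 (5.41), a receptor for immunoglobulin G, and Ace (5.32), angiotensin-converting enzyme, followed Treml4 (5.60), a gene of the gate. Pparg, a lipid-sensing nuclear receptor, was higher by 5.0, Bcl2a1c by 4.85, the phosphatase Dusp16 by 4.52 and Il1b, the gene of interleukin-1 beta, by 4.43. The lower side held Mmp8 (-6.97), Ly6a2 (-6.04), Fn1 (-5.99) and Clec5a (-5.43), an activating lectin receptor. Ccnb2 and Ctsg were both at -5.30, Bub1, a kinase of the spindle checkpoint, at -5.26 and the cyclin Ccna2 at -5.22.

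Nonclassical monocyte genes had 22 of 24 higher and 0 lower, with a median of 4.0, and Tcf7l2 (4.37), Nr4a1 (3.94), Itgax (2.6) and Cx3cr1 (1.75) were among them. Mitosis genes had 21 of 21 lower (median -4.32), with Birc5 at -5.14, Top2a at -5.11 and Mki67 at -4.33. DNA replication genes had 21 of 23 lower and 0 higher (median -2.11), with Rrm2 (-4.04), Rrm1 (-3.25), Cdc45 (-3.12) and Tyms (-3.05) in front. Primary granule genes had 9 of 13 lower (median -2.01), with Prtn3 (-4.59), Mpo (-4.12) and Elane (-4.07), while the granule proteoglycan Srgn was at 1.54. Classical monocyte genes had 8 lower and 2 higher of 18 (median -0.84), with Chil3 (-4.99) and Vcan (-4.43) lower and Lyz1 (1.35) and Clec4e (1.17) higher.

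Interferon-stimulated genes had 9 of 20 lower and 0 higher (median -0.82), with Cxcl10 (-2.70), Ifit1 (-2.07) and Ifit3 (-2.01) in front. Cholesterol synthesis genes had 5 of 14 lower, Fdps (-2.18), Sc5d (-1.66), Idi1 (-1.64), Sqle (-1.40) and Fdft1 (-1.36), with a median of -0.81. Trafficking genes had 5 higher and 3 lower of 17 (median 0.53), with S1pr5 (3.76), the receptor for marrow exit of patrolling monocytes, and Itgal (1.81) higher and Ccr1 (-4.34), Itga6 (-1.40) and Itgb7 (-1.19) lower. Genes shared by conventional dendritic cells had 3 higher and 1 lower of 9 (median 0.53), with Cd83 (2.20) higher and Id2 (-1.57) lower. Immediate early genes had 5 of 18 higher, with Nr4a1, Dusp1 (2.27) and Jun (1.36) in front (median 0.39). Fc and complement receptor genes had 3 higher and 1 lower of 10 (median 0.37), Cfp, the gene of properdin, being at -2.58. Myeloid transcription factors had 8 higher and 4 lower of 34 (median 0.35), with Bhlhe40 (2.70) and Pou2f2 (2.09) higher and Myb (-2.86), Id2, Irf8 (-1.32) and Id1 (-1.14) lower. Class II genes had 1 higher and 1 lower of 7, Cd74 (2.26) and H2-DMa (-1.83), with a median of 0.34, and type 2 dendritic cell genes 2 higher, Ltb (2.28) and Clec4a4 (1.79), and 4 lower of 10 (median -0.08), and both were called.

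Stem and early progenitor genes had a median of 0.24, which was called, but a mean of -0.11, with Myb, Adgrl4 (-2.62) and Cd34 (-1.35) lower and Sox4 at 1.25. Ribosome biogenesis genes had 5 of 21 lower, Myc (-3.05), Fbl (-1.40), Nop58 (-1.34), Wdr12 (-1.26) and Dkc1 (-1.04), with a median of -0.41, not called. Lysosome genes (-0.42), pattern recognition genes (0.08), plasmacytoid genes (0.12) and type 1 genes (0.00) were not called either. Against the direction of their lists stood Lgmn (1.74) among lysosome genes, Clec5a, Mefv (-2.46) and Tlr1 (-1.34) among pattern recognition genes, and Smim5 (-2.19) and Bst2 (-1.19) among plasmacytoid genes. After quantile normalization the split was 454 genes higher and 858 lower, and the stem and early progenitor call ended, while Bst2 was at -0.998. The Fc and complement receptor call ended without genes that other lists hold, and those of the class II and type 2 lists without members under the floor on every array.

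**Figure D3:**
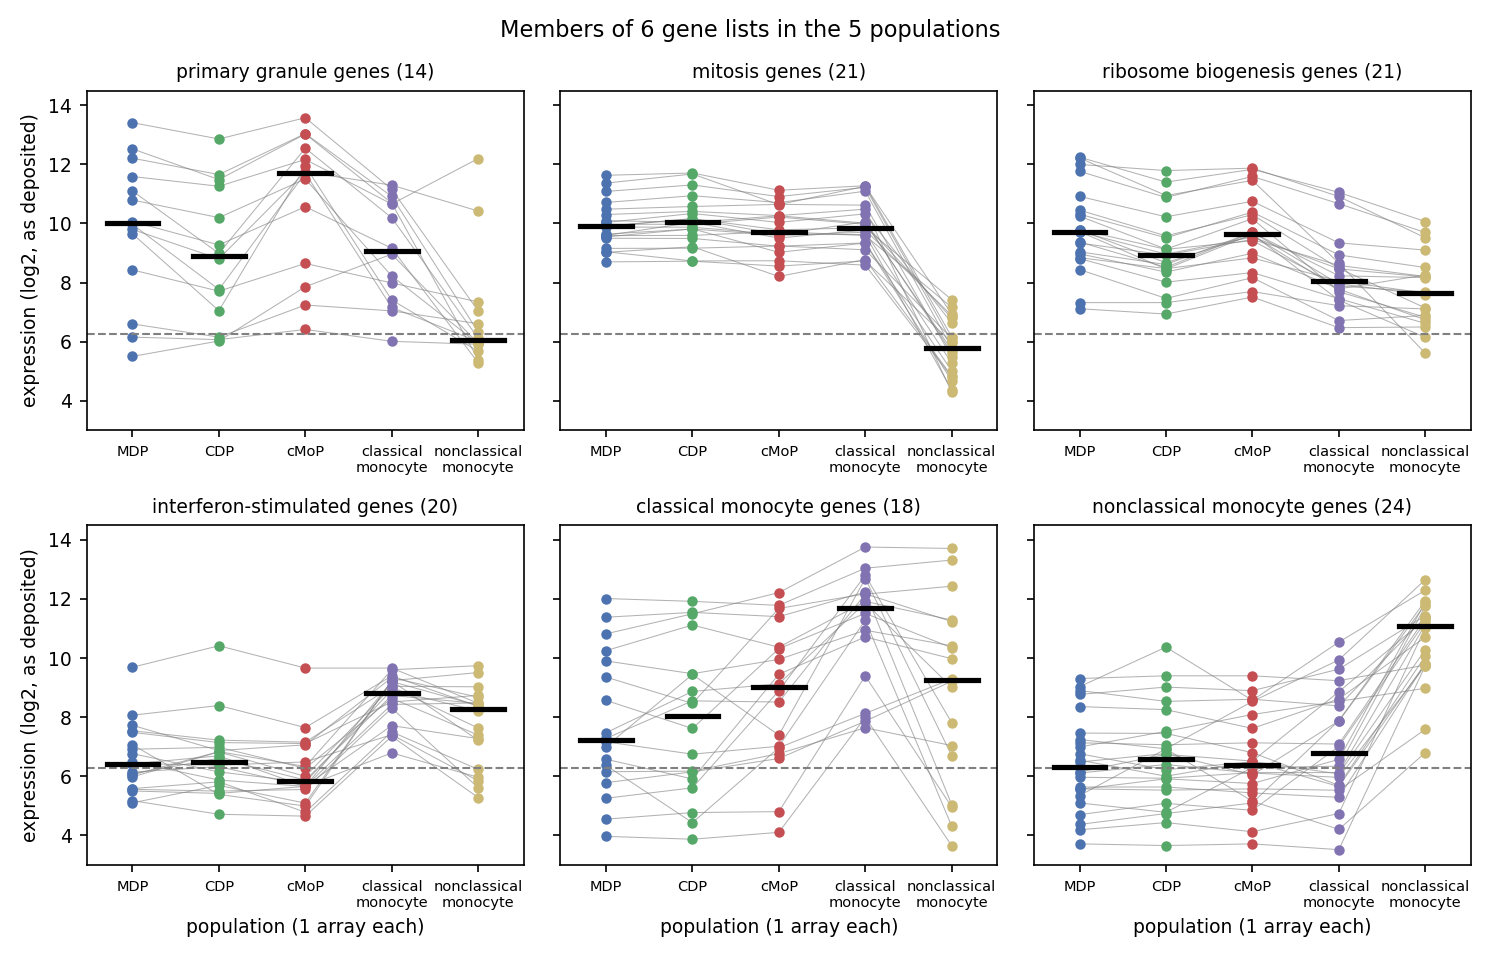
Log2 expression (vertical axis) of the members of 6 gene lists in the 5 populations (horizontal axis, 1 array each), with 1 point per gene, grey lines joining a gene's values, a black bar at each list's median and a dashed line at the floor. The median of the mitosis genes is 9.73 in cMoP, 9.86 in classical monocytes and 5.79 in nonclassical monocytes, while that of the ribosome biogenesis genes is 9.64, 8.05 and 7.64.

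Markers of other cells that a marrow sort could hold were mostly dim. In no comparison did the B cell, T and NK cell, erythroid or megakaryocyte list have more than 6 members past the floor. Their medians lay between -0.12 and 0.24, and 1 of them was called, megakaryocyte and platelet genes in CDP against MDP (0.24, with 0 of 4 past the threshold). Single members did stand out. Klrd1 (1.95), Thy1 (1.0, and 0.95 after centring) and Cd22 (1.38), an inhibitory B cell receptor, were higher in CDP than in MDP, and the carbonic anhydrase Car2 was lower (-1.54). In classical monocytes against cMoP the transferrin receptor Tfrc was at -2.37, Car1 at 1.69 and Cd79b at -1.09. Macrophage genes had medians of 0.21 in CDP against MDP and 0.01 in classical monocytes against cMoP, both called. In the latter Hmox1 (2.97), Adgre1 (2.29) and Siglec1 (1.06, and 0.98 after quantile normalization) were higher, and the median was -0.04 after quantile normalization. In the other comparisons the macrophage medians were 0.05, -0.08 and 0.01, not called.

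Neutrophil genes had medians of 0.09 in CDP against MDP, 0.10 in cMoP against MDP and 0.00 in cMoP against CDP, not called, while in these comparisons 1, 3 and 4 members were higher and 2, 0 and 0 lower of 6, 7 and 7 past the floor. In CDP against MDP, S100a8 was at 1.03 (0.97 after centring) and Cxcr2 and Csf3r (-1.23) were lower. S100a8, Lcn2 and S100a9 (1.72) were higher in cMoP than in MDP, and S100a8, Lcn2 (2.74), Csf3r (1.55) and Cxcr2 (1.51) higher than in CDP, and the list means were 0.67 and 0.64. These members were higher beside the primary granule genes. The list median was 0.06 in classical monocytes against cMoP and -0.06 in nonclassical against classical monocytes, both called. In classical monocytes S100a9 (3.66), Cd177 (2.99), Ngp (1.53), Lcn2 (1.48) and S100a8 (1.41) were higher than in cMoP and Cxcr2 lower, and the median was -0.00563 after quantile normalization. In nonclassical monocytes S100a8 (-4.79), Lcn2 (-4.54), S100a9 (-3.89) and Cd177 (-2.99) were lower, and the call ended without genes that other lists hold. The list was called higher in cMoP than in MDP under all alternatives but centring. Basophil, mast cell and eosinophil genes had called medians of -0.01 in CDP against MDP (0.02 after quantile normalization), 0.04 in cMoP against CDP and 0.31 in nonclassical against classical monocytes, the first 2 of which ended without members under the floor on every array. Hdc was higher in cMoP than in MDP by 2.52, and the basophil protease Mcpt8 differed by -1.99 between classical monocytes and cMoP. The other 2 medians of that list, 0.01 and -0.09, were not called. Over all lists and comparisons 85 of the 135 medians of lists with enough members were called, and 21 of the 85 were under 0.2 in size. The percentile limits would give 6.75 calls for independent lists of unrelated genes. That number is no reference here, since the lists hold co-regulated genes, share members and were compared on the same arrays.

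Genes that led a single population were most numerous in nonclassical monocytes, with 318, against 120 in classical monocytes, 31 in cMoP, 27 in MDP and 22 in CDP. MDP was led by Angpt1, which was 2.43 above the next array, Mc5r (1.94), Tespa1 (1.88), Ctla2a (1.85) and Prrg4 (1.76). CDP was led by Cd7 (3.12), Clec9a (2.56), Siglech (1.98), Klrd1 (1.95) and Upk1b (1.94), and cMoP by Hdc (2.52), Ms4a3 (2.29), Mgst2 (1.99), Mgam (1.86) and Prss57 (1.76). Classical monocytes were led by Vcan (4.43), Mmp8 (4.12), Chil3 (3.90), Ccr1 (3.89) and S100a9 (3.66), and nonclassical monocytes by Cd36 (6.28), Fabp4 (6.02), Treml4 (5.60), Fcgr4 (5.41) and Lilra5 (5.38).

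Across the boundary between progenitors and monocytes, 87 genes were higher on all 3 progenitor arrays than on both monocyte arrays, and 263 were the reverse. The widest progenitor gaps were those of Nedd4 (3.18), a ubiquitin ligase, Ccnd2 (3.03), Cd34 (2.96), B3gnt5 (2.94), Adgrg3 (2.75), Kit (2.37), Il12a (2.34), Igfbp4 (2.32), Myc (2.29) and Myb (2.26). The widest monocyte gaps were those of Klra2 (5.49), Clec4a3 (5.28), Tlr13 (5.04), Clec4a1 (4.96), Ms4a4a (3.91), Ccl6 (3.79), Ifitm6 (3.61), the kinase Fgr (3.52), Apoe (3.24), the gene of apolipoprotein E, and Lilr4b (3.18). The arrays on each side are different populations and not replicates of one another.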

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

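No tests were chosen after the result was seen in this part, since all alternatives were planned before. Quantile normalization, centring, no floor and the mean of a gene's probe sets kept each of the 17 counts within 1.5 times. A floor at the upper quartile (7.93) moved 4 of them, to 61 genes lower in CDP than MDP, 73 lower in cMoP than MDP, 149 lower in cMoP than CDP and 11 leading MDP, since fewer genes pass it. A threshold of 2 log2 units lowered all 17 by its construction. The numbers higher and lower became 21 and 7 for CDP against MDP, 23 and 20 for cMoP against MDP, 40 and 45 for cMoP against CDP, 197 and 57 for classical monocytes against cMoP, and 116 and 313 for nonclassical against classical monocytes. Leading genes became 1, 2, 2, 33 and 93 for MDP, CDP, cMoP, classical and nonclassical monocytes, and progenitor and monocyte genes 16 and 61. In 5 cases a called list's median changed sign, each near 0, and the cause was not tested. Quantile normalization gave 0.0200 for basophil, mast cell and eosinophil genes in CDP against MDP, 0.0222 for type 1 dendritic cell genes in cMoP against MDP, and -0.00563 and -0.0381 for neutrophil and macrophage genes in classical monocytes against cMoP. Quantile normalization moved the median difference of all named genes in the same directions, by 0.0415, 0.0978 and -0.0710 in these comparisons. It was run over all 35556 probe sets, among them the unlisted block of 6617 that was lower on the cMoP array. It is thus no neutral scaling for comparisons with cMoP, and the part of the block in these shifts was not tested. Without genes that other lists hold, the type 1 median in cMoP against MDP was 0.00142. Without centring, which moves a list and its random lists alike, 537 other list values kept their call or its absence, 20 lost it and 18 gained one, and the lists that lost it are named beside their results. Of the values of named genes under the scaling and probe set alternatives, 1833 stayed on their side of the 1 log2 unit threshold, 0 past it changed sign, 19 moved under it and 8 moved past it. Much of this was fixed in advance, since most named genes were picked for large differences. The mean of probe sets, which gave 620 of the 1833, can change only genes with several. Centring moved all genes of a comparison alike, by at most 0.0589. Between scalings the share of higher among changed genes moved most with centring in CDP against MDP, from 52.2% to 42.2%. The pseudocount alternative was not run because the values are logarithmic. No paired analysis was possible because each population has 1 array, so no replicate could be left out either. Signal near the floor limits what can be seen of dim genes, and without replicates no alternative replaces an estimate of the spread.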

Other observations

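The tests in this part were chosen only after the result was seen, except those of scaling for the split between the monocyte subsets and of the named targets of the unlisted probe sets.

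Median levels of lists of general cell processes ranked the 5 populations in different orders. The middle member can be another gene on each array, so these levels do not follow single genes and can differ from the gene-wise differences above. The median of the lysosome genes was 9.16 in MDP, 9.93 in CDP, 10.1 in cMoP, 11.1 in classical and 10.6 in nonclassical monocytes. The trafficking and adhesion genes had medians of 7.64, 8.99, 8.34, 9.61 and 10.6 in the same order, though their gene-wise median between CDP and MDP was only 0.31. Cholesterol synthesis genes lay at 7.37, 7.33, 7.43 and 7.58 on the first 4 arrays and at 6.82 in nonclassical monocytes. Immediate early genes lay at 7.03, 7.02, 7.10, 7.61 and 8.45. Their gene-wise differences went otherwise among the progenitors, with called medians of 0.24 in CDP against MDP and -0.27 in cMoP against CDP.

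Mitosis genes were as high in classical monocytes as in cMoP, with a median at 111% of the cMoP level, while all 21 were at least 2 log2 units lower in nonclassical monocytes. Progenitors carried into the classical gate would bring their own transcripts, and nearly all RNA would have to be theirs to give this mitosis level. However, 10 progenitor genes at least 1 log2 unit above the floor in cMoP had a median difference of -2.19 (quartiles -2.51 and -1.24). Of these, 9 fell by more than any mitosis gene. Their median stood at 22.0% of the cMoP level and Cd34 at 8.38%. These values argue against progenitors as the whole source of the mitosis signal, while a smaller share of carried-over cells is not excluded. A ceiling of the measurement is argued against by the highest mitosis gene, at 11.28 in classical monocytes, where the 99th percentile of that array is 12.80. Dividing cells among marrow classical monocytes are a candidate explanation that cannot be told apart from others, since DNA replication genes, a list with 0 genes in common with the mitosis list, had a median of -0.599 between classical monocytes and cMoP, neither near the mitosis median of 0.15 nor 1 log2 unit under it. Between nonclassical and classical monocytes the replication median was -2.11, with 21 of 23 genes lower. Both lists were thus far higher on the classical than on the nonclassical array. Whether dividing cells in the classical gate would be monocytes or late precursors that had lost Kit was not tested.

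Of the genes that differed between the monocyte subsets, 26.6% were higher in nonclassical monocytes and the rest lower. Scaling between the arrays could shift such a split, but the highest share over quantile normalization and centring was 34.6%, still well under an even split. A wider loss of proliferation genes was not tested. Of the lower genes 708 (68.7%) were also 1 log2 unit under all 4 other arrays, and of the higher genes 318 (85.3%) were 1 log2 unit over all 4. A loss of expression that belongs to the nonclassical population, or a property of that 1 array, stays open, since population and array cannot be separated here.

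The unlisted block of 6617 probe sets had a mean difference of -0.413 between cMoP and MDP. Scaling between the arrays is argued against, since named probe sets matched on mean value had a mean difference of 0.0151 (median of 1000 draws). A shift of this size in dim or unnamed probe sets at large is argued against too, since the other unlisted probe sets had a median of -0.0208 over the 1933 past the floor and of 0 over all 5529. Among those 1933, however, the few that differed by 1 log2 unit or more leaned the same way, with 68 lower and 13 higher in cMoP. Less unspliced RNA or genomic DNA in the cMoP sample is a candidate explanation that cannot be told apart from others. The check on named targets could not decide it. The block was defined by its absence from the annotation, so a count of 0 named targets was fixed in advance. No biological explanation was tested.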
